A study of Mus musculus with 15 samples.

How the data were processed

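Splenic Treg of 6-week-old male mice were measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with probes along its exons. Per the sample labels, cells were sorted on CD3, TCR beta, CD4 and the green fluorescent protein of the Foxp3 locus, with cells positive for CD8, B220, CD11b, CD11c or Gr1 gated out. Cells of several mice were pooled for each array, and RNA of 40000 to 50000 cells was extracted with TriZol, amplified and labelled with the manufacturer's whole transcript kit. Control, N1c and RBPJdel cells were sorted on a MoFlo and N1c_RBPJdel cells on a FACSAria.

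The deposited values are array intensities, which the authors summarised per transcript cluster with RMA in Affymetrix Power Tools, per the submitters' processing notes. The versions of both, the annotation release and any filter are not given in the sources used here. The table held 24922 features on 15 arrays, with values from 5.61 to 18029.7 and a median per array of 107.1 to 117.2, which is a linear and not a log2 scale. Values were converted to log2 and were otherwise used as they are. Of the features, 21425 named 1 gene, 1399 named several and 2098 named none, and only those naming 1 gene entered the comparisons. The Entrez ID of 21347 of them matched the mouse reference table (GRCm38.p6). For 921 genes with more than 1 feature the one with the highest mean over all arrays was kept, which left 19752 genes, and no gene was removed for low intensity. Members of a list whose features named several genes or none were not measured in this sense. The number of arrays limits the precision. Correlations between arrays lay between 0.957 and 0.996, and no pair of arrays was a duplicate.

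Groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with 11 residual and 6.15 prior degrees of freedom. The p-values are two-sided and adjusted by Benjamini-Hochberg over the 19752 genes within a comparison, with a threshold of 0.05. They measure the spread between arrays of pooled mice. The 6 comparisons were N1c against control, RBPJdel against control, N1c_RBPJdel against each of the other 3 groups, and the interaction, which is the difference between the N1c effect with the deletion of Rbpj and that without it. There were 17 gene lists and 9 lists of cell type markers, 26 in all, tested with camera of limma at a preset correlation between genes of 0.01 and adjusted over the 26 lists within a comparison. The test was repeated with a correlation estimated from the data. Members were counted past the threshold over all genes and again with p adjusted over the list alone. The share of the N1c change left in N1c_RBPJdel was the difference of N1c_RBPJdel from control divided by that of N1c from control, as a median over the genes called in N1c against control. Overlaps between comparisons that share arrays were also counted with the shared arrays split into separate pairs. Those splits of the overlap counts were chosen after the data were seen.

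The named genes are Notch1, Rbpj and Foxp3 and those chosen by rank. For N1c against control, RBPJdel against control and N1c_RBPJdel against N1c these are the 10 with the largest rise and the 10 with the largest fall among the genes past the threshold whose arrays do not overlap between the groups. Where fewer passed, places up to 5 per direction went to the smallest p. For the other 3 comparisons the rule took 5 and 5, for the interaction without the condition on overlap. From each list, up to 4 members past the threshold were taken for the first 3 comparisons by smallest p. Symbols of predicted genes, receptor gene segments, olfactory and vomeronasal receptors and small RNAs were skipped. The rule gave 121 genes. Genes named outside it were chosen after their values were seen. These were Nrarp, Hey2, Myc, Naip5, Abcb1a, H2bc9 and Lgmn in N1c, Hes1, Hey1 and Heyl in RBPJdel, and Il10 in N1c_RBPJdel against N1c. They also include H2-Ea throughout, Heyl, Hey1 and Nrp1 in the interaction, and several in N1c_RBPJdel against control or RBPJdel, where the text says so.

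Arrays of different groups carry the same replicate numbers, and the residuals of arrays with the same number were correlated to see whether the numbers pair them. The rule called groups paired where r was above 0.1 for each shared number. For N1c and control r was 0.417, 0.341 and 0.497 (numbers 2, 4 and 5), and these groups met the rule. For RBPJdel and control r was 0.166, 0.0711 and 0.417, which did not meet it, and the other groups were not paired either. The replicate block among the alternatives was nevertheless fitted to all groups. It therefore also tied arrays that the rule did not pair. Over all groups the median r was 0.139 for 16 pairs of the same number and -0.0619 for 68 pairs of different numbers.

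Alternatives were run 1 at a time. They were quantile normalization and cyclic loess of the deposited values, genes brighter than the median gene alone, the mean of the probe sets of a gene, a prior variance with a trend on the mean, array weights, the replicate number as a block, a log2 change of at least 1, an adjusted p of 0.1, a fit of the 2 groups alone and each array left out in turn. Chosen after seeing the data were the interquartile range of log2 intensities of each array as a covariate, N1c_RBPJdel 2 alone for its group, control 5 and N1c 5 left out together, and 4 settings of the list tests. Counts of genes had 28 settings besides the reported one. Where 1 array stood for a group it was assumed to vary like the other groups. Quantile normalization and cyclic loess moved the median change of all genes by less than 0.1 on the log2 scale.

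The procedure was tested on simulated data with 200 changed genes. All simulated genes and arrays varied independently, unlike those of the data, so the shares below give no error rate for correlated genes or arrays. Changes of 0.5 on the log2 scale were recovered for 46.3% of genes in N1c against control, 47.8% in RBPJdel against control, 41.8%, 32.8% and 38.8% in N1c_RBPJdel against N1c, control and RBPJdel, and 28.4% in the interaction. For changes of 1 these shares were 92.5%, 94.0%, 88.1%, 88.1%, 95.5% and 74.6%. For changes of 2 they were 100% in the first 5 comparisons and 93.9% in the interaction. Of the genes called, 3.70% to 8.70% had not been changed. Camera called all of 100 simulated lists with 6 of 20 members changed by 1 and 0% of unchanged lists, and a true share left of 0.3 was recovered as 0.304.

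The text also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots. Features naming several genes or none were left out of the comparisons and counted apart. The scans of the arrays were not used here, and no result rests on probes finer than the transcript cluster. Near-identical genes such as Naip5 and Naip6, H2bc9 and its histone relatives, Ms4a4c, the granzymes and Zfp979 can share signal on these probes.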

Results

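Gene expression was measured in splenic regulatory T cells (Treg) of mice in which Notch signalling had been switched on, disabled or both in Foxp3-expressing cells. Cells that expressed green fluorescent protein from the Foxp3 locus were sorted from 6-week-old males, and each array carried amplified RNA of 40000 to 50000 cells pooled from several mice. The 15 arrays fell into 4 groups named after the genotype labels. The control group carried the Foxp3EGFPCre allele alone (4 arrays). The N1c group also carried R26N1c, from which Cre releases the active intracellular part of Notch1 (4 arrays). In the RBPJdel group the label gives a deletion of the gene of RBPJ, the DNA-binding protein through which that fragment acts on transcription (4 arrays). The N1c_RBPJdel group carried both changes (3 arrays). Values are geometric mean intensities, and changes are differences of group means on the log2 scale with the limma standard error (SE) over 19752 genes. The N1c_RBPJdel cells were sorted on a FACSAria and all others on a MoFlo, so that the sorter and the genotype cannot be told apart in the comparisons of that group.

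Rbpj itself (transcript cluster 10521913, chromosome 5) had a mean intensity of 497 in control and 521 in N1c arrays, against 267 in RBPJdel and 209 in N1c_RBPJdel arrays. It fell by 0.90 ± 0.12 (SE, n = 4 and 4) in RBPJdel against control (adjusted p = 0.00213). It also fell by 1.32 ± 0.13 (n = 3 and 4) in N1c_RBPJdel against N1c and by 1.25 ± 0.13 in N1c_RBPJdel against control. Notch1 lay at 1227 in control, 1252 in N1c, 1326 in RBPJdel and 1008 in N1c_RBPJdel arrays, and Foxp3, the factor that defines Treg, at 4979, 4342, 5333 and 4219.7; neither passed the test in any of the 6 comparisons. With the replicate block Notch1 passed it in N1c_RBPJdel against the other 3 groups (-0.49 against N1c, adjusted p = 0.0235, range 0.0235 to 0.993 over the alternatives). Foxp3 did so in N1c_RBPJdel against RBPJdel with the block and without N1c_RBPJdel 2 (adjusted p = 0.0495 and 0.0487, range 0.0487 to 0.830). The pairing rule did not pair N1c_RBPJdel with any group, so the calls with the block rest on a pairing that it rejected. With the mean of the probe sets of a gene in place of the brightest probe set, the change of Rbpj in RBPJdel was -0.41 and was not called (adjusted p = 0.320, range 3.1e-05 to 0.320 over the alternatives). That mean takes in a second, dim probe set of Rbpj (10521911, mean intensity 56.2), which changed by 0.09 in RBPJdel against control.

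**Figure D1:**
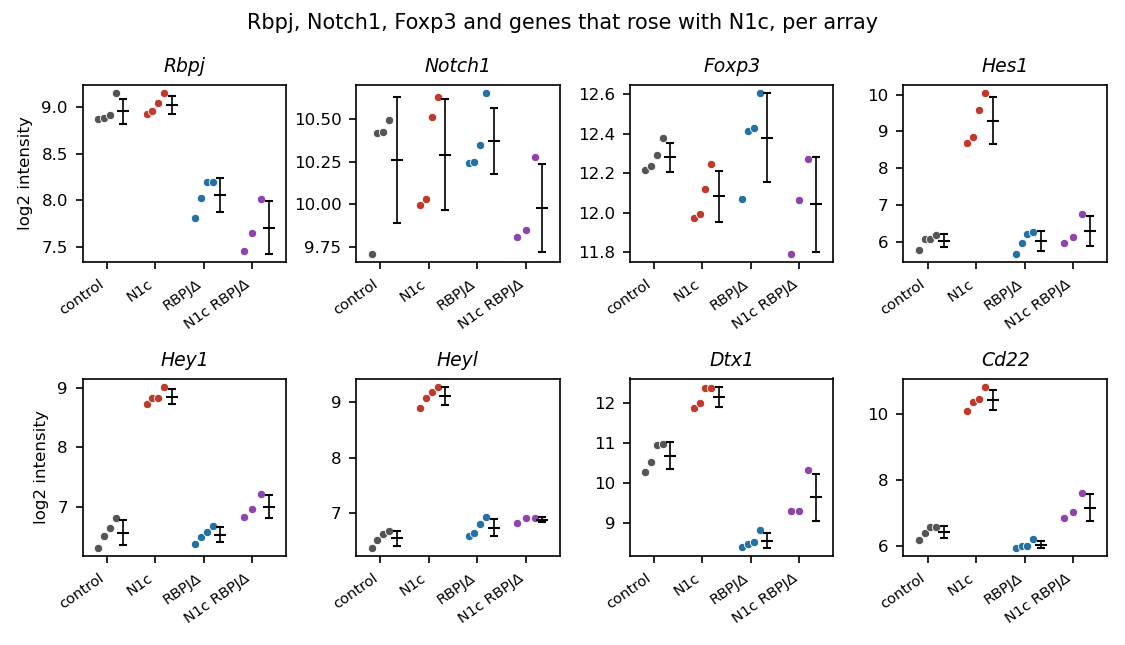
Log2 intensity (vertical axis) of 8 genes on each array of the 4 groups (horizontal axis); points are arrays and the black marks show the mean ± SD. Hes1, Hey1, Heyl, Dtx1 and Cd22 were higher on all 4 N1c arrays than on any control array, and Rbpj was lower on all RBPJdel and N1c_RBPJdel arrays.

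Comparing N1c with control asked what active Notch1 does in Treg. Among the genes that rose were Cd22, a lectin receptor best known from B cells (transcript cluster 10562132, chromosome 7), and Hes1, a transcriptional repressor and direct Notch target (10434925, chromosome 16). Cd22 went from 86.1 to 1379.7, a log2 change of 4.00 ± 0.16 (n = 4 and 4), and Hes1 from 65.6 to 626, a change of 3.25 ± 0.245. Dnase1l3 rose by 3.45, Atp8a2 by 3.25, the phosphodiesterase gene Pde3b by 3.16, Slc16a5 by 2.55 and Prag1 by 2.36. The repressors Heyl and Hey1 rose by 2.57 ± 0.11 and 2.27 ± 0.12. Among the genes that fell, Nrp1, a semaphorin receptor used as a marker of thymus-derived Treg, went from 1358 to 461, a change of -1.56 ± 0.12. Ms4a4c changed by -1.52, Fgl2 by -1.37, L1cam by -1.34, Sytl2 by -1.31, Rln3 by -1.31, Slc25a24 by -1.30, the noncoding RNA gene Flicr by -1.28 and Ctsw by -1.22. Of 19752 genes, 326 passed adjusted p 0.05, 185 higher and 141 lower in N1c, and 84 of them changed by at least 1 on the log2 scale. The 2 groups did not overlap for 5.73% of all genes, against 2.86% by chance. Arrays of N1c and control with the same number went together (r = 0.341 to 0.497 between the residuals of the 3 pairs). With the number as a replicate block 494 genes were called. That block was fitted to all groups, including those the rule did not pair, and a paired fit of N1c and control alone was not run. Array weights gave 733 genes, and without control 4 there were 217.

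Of 15 measured members of the Notch target list, 6 rose and 1 fell in N1c (adjusted p = 7.3e-11, camera; adjusted p = 0.00439 with an estimated correlation; 6 and 1 adjusted over the list alone). Beside Hes1, Hey1 and Heyl these were Dtx1, a regulator of Notch itself, which rose from 1639 to 4537 (1.47 ± 0.21), and Nrarp (1.47), which was named after its values were seen, as were the next 2 genes. The call of Hey2 (0.66) was lost without N1c 4 or 5 and without control 2 or 3 (adjusted p = 0.0631 to 0.0838; 0.00257 to 0.106 over the alternatives). That of Myc (-0.54; adjusted p = 0.0496) was lost without any 1 of N1c 1, 2, 4 and 5, control 2, 3 and 4, RBPJdel 1, 2 and 3 and N1c_RBPJdel 1 (0.000969 to 0.174 over the alternatives). None of the 28 members of the list of Notch pathway parts passed the test (0 rose and 2 fell adjusted over the list alone; adjusted p = 0.643).

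Treg effector genes rose in N1c: 4 of 20 members of the effector Treg list (11 rose and 1 fell adjusted over the list alone; adjusted p = 2.3e-12, and 0.0931 with an estimated correlation). The anti-inflammatory cytokine gene Il10 rose from 82.9 to 440.2 (2.41 ± 0.39), the cytotoxic protease gene Gzmb from 206 to 785 (1.93 ± 0.25) and the integrin gene Itgae by 1.14 ± 0.14. In the Treg signature list 3 of 26 members rose, the same Il10, Gzmb and Itgae, and 4 fell, among them Nrp1 and Fgl2 (4 and 6 adjusted over the list alone); the list was called lower (adjusted p = 0.0296, and 0.405 with an estimated correlation). In the resting T cell list 2 of 14 members rose and 4 fell (2 and 6 adjusted over the list alone), with Actn1 up by 0.81 and the survival gene Bcl2 at -0.61, and the list was called lower (adjusted p = 0.00316, and 0.230 with an estimated correlation). In the Th1 list 4 of 15 members rose, among them Fasl (1.52) and Il12rb2 (1.17), and 2 fell, among them Il18r1 (-1.16), with 7 and 3 adjusted over the list alone (adjusted p = 0.00072, and 0.228 with an estimated correlation). The Tfh list had 3 of 12 members up, with Cxcr5 at 1.37 and Slamf6 at 0.70 (4 and 1 adjusted over the list alone; adjusted p = 0.00754, and 0.228 with an estimated correlation). Homing receptors went both ways, 5 of 24 up and 4 down (6 and 7 adjusted over the list alone; adjusted p = 0.413; median -0.02 and mean 0.07). Gpr183, an oxysterol receptor that positions lymphocytes, rose by 1.42 and Gpr15 by 1.02, while the integrin gene Itgb1 changed by -1.10 and Ccr6 by -0.81. Among the brighter genes alone the calls of the Treg signature, Th1 and Tfh lists were lost (adjusted p = 0.131, 0.123 and 0.243). Over the list alternatives adjusted p ran from 0.0152 to 0.405, 2.9e-05 to 0.228 and 0.00739 to 0.243 for these 3.

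The cell cycle list was called higher in N1c (adjusted p = 6.2e-19, and 0.228 with an estimated correlation), with 2 of 35 members past the test over all genes and 22 higher adjusted over the list alone. Its median change was 0.48, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose by 1.18; that call was lost without N1c 1 (adjusted p = 0.0511) and without N1c 5 (adjusted p = 0.0558; 0.00136 to 0.142 over the alternatives). NK cell markers had 3 of 11 members up (adjusted p = 0.0210, and 0.230 with an estimated correlation), with Gzma at 0.90 and Prf1 at 0.72, both genes of cytotoxic granules; these calls were lost in the fit of the 2 groups alone (adjusted p = 0.0580 and 0.0675, the highest over the alternatives, with 2.7e-05 and 0.000314 the lowest), and that of the list with the replicate block (adjusted p = 0.0638, range 0.0276 to 0.230). The list of immediate early and heat shock genes was called higher (0 of 16 members past the test; adjusted p = 0.0232, and 0.540 with an estimated correlation) and that of mTOR and PI3K-Akt genes lower (0 of 23; adjusted p = 0.0210, and 0.316 with an estimated correlation); both calls were lost among brighter genes (adjusted p = 0.0826 and 0.123, ranges 0.000836 to 0.540 and 0.0115 to 0.316). The other lists were not called. The counts up and down were 2 and 1 of 14 Th2 genes (adjusted p = 0.0770), 1 and 1 of 12 Th17 genes (0.707), 1 and 1 of 18 apoptosis genes (0.209), 2 and 1 of 9 CD8 T cell markers (0.172) and 1 and 1 of 8 conventional CD4 T cell markers (0.130). Of 15 B cell markers 1 passed, Cd22 (0.935; the median, -0.05, and the test pointed down and the mean, 0.17, up). No member passed among 26 interferon response genes (0.935), 18 glycolysis genes (0.707), 21 ribosomal protein genes (0.935), 15 myeloid markers (0.935), 13 neutrophil markers (0.706), 11 dendritic cell markers (0.464), 9 erythroid markers (0.935) and 8 platelet markers (0.935). At an unadjusted p under 0.05 there were 1621 genes in this comparison.

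**Figure D2:**
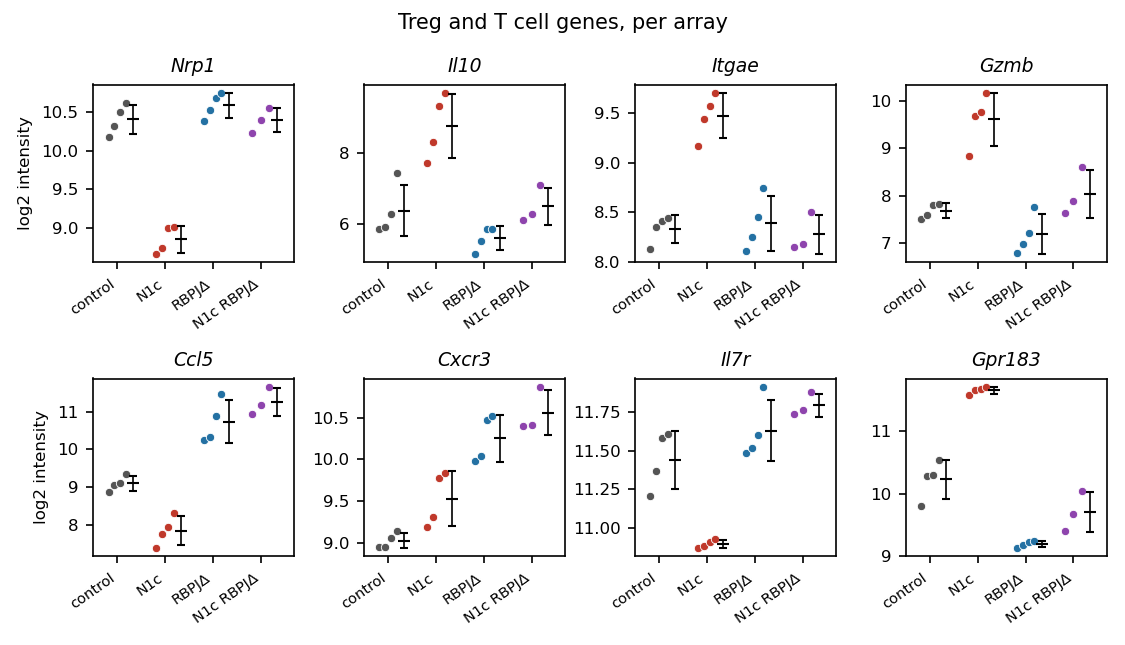
Log2 intensity (vertical axis) of 8 Treg and T cell genes on each array of the 4 groups (horizontal axis); points are arrays and the black marks show the mean ± SD. Nrp1 and Il7r were lowest and Il10, Itgae, Gzmb and Gpr183 highest on the N1c arrays, and Ccl5 ran from 230 in N1c to 2453 in N1c_RBPJdel (group means).

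Comparing RBPJdel with control asked what Treg lose when the gene of the DNA-binding partner of Notch is deleted. The largest fall was that of Dtx1, from 1639 to 378 (-2.12 ± 0.21, n = 4 and 4; adjusted p = 0.000116). Others that fell were Penk, which encodes proenkephalin (-1.80), Prag1 (-1.20), Naip6 (-1.14), Gpr183 (-1.04), the drug efflux pump gene Abcb1a (-1.02) and Naip5 (-1.01). Naip5 and Naip6 are close relatives whose probes can share signal. The chemokine gene Ccl5 rose from 547 to 1694 (1.63 ± 0.24), the protease gene Lgmn from 213 to 596 (1.49 ± 0.13), Cxcr3, a chemokine receptor of Th1-like cells, from 523 to 1219 (1.22 ± 0.16), and Kcnf1 by 1.20. In all, 22 genes passed the test, 7 higher and 15 lower, with 1331 at an unadjusted p under 0.05; array weights gave 189. The groups did not overlap for 5.89% of genes, against 2.86% by chance.

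Of 15 Notch targets only Dtx1 passed in RBPJdel (adjusted p = 0.993; the median, 0.06, pointed up and the mean, -0.10, and the test down), and Hes1 (65.6 and 65.2), Hey1 (95.2 and 92.8) and Heyl (a log2 difference of 0.20) did not pass the test. Hes1 and Hey1 lay below the array medians (107.1 to 117.2) already in control, so that a fall would be hard to see. None of the 26 Treg signature genes passed (3 and 2 adjusted over the list alone, and adjusted p = 0.993 in camera). The Th1 list was called higher, with Ccl5 and Cxcr3 past the test out of 15 (5 and 1 adjusted over the list alone; adjusted p = 0.00274, and 0.572 with an estimated correlation). The cell cycle list was also called higher (0 of 35 past the test, and 0 adjusted over the list alone; median 0.34; adjusted p = 2.7e-09, and 0.572 with an estimated correlation). CD8 T cell markers, with Ccl5 up out of 9, were called higher (adjusted p = 0.0353, and 0.572 with an estimated correlation), which was lost with the array range as a covariate (adjusted p = 0.106) and with N1c_RBPJdel 2 alone for its group (adjusted p = 0.0650, range 0.00174 to 0.572). The mTOR and PI3K-Akt list (0 of 23; adjusted p = 0.0362, and 0.572 with an estimated correlation) and the immediate early list (0 of 16; adjusted p = 0.0441, and 0.849 with an estimated correlation) were called lower, and both calls were lost after quantile normalization (adjusted p = 0.174 and 0.112, ranges 0.00332 to 0.572 and 0.0768 to 0.849).

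A part of the genes that rose in N1c fell in RBPJdel. Of the 15 genes that fell in RBPJdel, 10 rose in N1c, against 0.140 expected of independent lists. Examples are Dtx1 (1.47 in N1c and -2.12 in RBPJdel), Prag1 (2.36 and -1.20), Naip5 (1.78 and -1.01), Abcb1a (1.66 and -1.02) and Gpr183 (1.42 and -1.04). Ccl5 did the reverse, with -1.25 ± 0.24 in N1c and 1.63 in RBPJdel; its call in N1c was lost without control 5 and N1c 5 together (adjusted p = 0.0650; 0.00152 to 0.0650 over the alternatives). Lgmn rose in both groups (1.39 and 1.49). H2bc9 did so too (0.61 and 0.76), with calls that 9 or more alternatives ended in each (adjusted p 0.00182 to 0.194 in N1c and 0.00444 to 0.170 in RBPJdel over the alternatives). Naip5, Abcb1a, Lgmn and H2bc9 in N1c were named after their values were seen. Of 13 genes called in both comparisons 11 changed in opposite directions. The comparisons share the control arrays; with the controls split into separate pairs, a median of 5.5 genes (2 to 10) changed in opposite directions and 1 in the same direction, against 0.0553 and 0.0409 expected of independent lists. Across all genes, which are not independent replicates, the log2 changes had r = 0.184. Simulated data with no effect, the same shared controls and otherwise independent arrays gave 0.498. Since residuals of arrays with the same number were correlated, which enters r with shared and with split controls, 0.498 is no exact reference and r alone does not show opposite changes. With the controls split the mean r was -0.0616, among brighter genes it was 0.120, and it was 0.277 without control 2 and 0.287 without control 3.

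Comparing N1c_RBPJdel with N1c asked how much of the response to active Notch1 needs RBPJ. Cd22 fell by 3.27 ± 0.17 (n = 3 and 4) and Hes1 fell by 3.00 ± 0.26. Prag1 changed by -3.12, Dnase1l3 by -3.10, Atp8a2 by -3.03, Pde3b by -2.86, the tubulin gene Tubb2b by -2.77 and Dtx1 by -2.51. The changes of Heyl (-2.23), Gpr183 (-1.95), Hey1 (-1.84), Actn1 (-1.78) and Itgae (-1.19) also passed the test. Ccl5 rose by 3.42 ± 0.26, Fgl2 by 2.52, Rln3 by 2.07, Ctsw by 1.67, Nrp1 by 1.55 ± 0.13, from 461 to 1348, and Il18r1 by 1.49. Outside the genes that had moved in N1c against control, the carbonic anhydrase gene Car1, a member of the erythroid list, rose by 2.60 ± 0.37 (852, 400.0 and 137 on the 3 arrays, 59.4 in N1c, and a change of 1.98 to 3.30 over the alternatives), and Atp5md, which encodes a small subunit of the mitochondrial ATP synthase, fell by 2.52, from 3896 to 680. Of 15 Notch targets 5 fell (5 adjusted over the list alone; adjusted p = 7.3e-06, and 0.0531 with an estimated correlation).

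Other T cell genes moved with them in N1c_RBPJdel against N1c. In the Treg signature list 8 of 26 members rose, among them Nrp1, Fgl2, Tigit (0.99) and Klrg1 (0.99), and 3 fell, Itgae, Il10 and Gzmb (11 and 5 adjusted over the list alone); the list was not called on the deposited values (adjusted p = 0.122) and was called higher after quantile normalization (adjusted p = 5.6e-05, range 5.6e-05 to 0.492). Il10, named here after its values were seen and not followed over the alternatives, changed by -2.29. The fall of Gzmb, -1.57, was lost with N1c_RBPJdel 2 alone for its group (-1.01, adjusted p = 0.157; 0.000257 to 0.157 over the alternatives). Effector Treg genes went both ways, 5 of 20 up, with Cxcr3 at 1.03, and 4 down (6 and 6 adjusted over the list alone; adjusted p = 0.981; the median was 0.02 and the mean -0.04). In the resting T cell list Il7r, the receptor of interleukin 7, rose by 0.90 and 4 of 14 members fell (1 and 6 adjusted over the list alone; adjusted p = 0.00253, and 0.416 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.126, range 0.00427 to 0.416). In the cell cycle list 12 of 35 members fell (25 adjusted over the list alone; adjusted p = 1.0e-12, and 0.416 with an estimated correlation). Rrm2, of nucleotide synthesis, changed by -1.34, a call lost with N1c_RBPJdel 2 alone (adjusted p = 0.110, range 1.3e-06 to 0.110).

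Markers of some other blood cells were also higher in N1c_RBPJdel than in N1c. Of 15 B cell markers 7 rose, among them Cd79a (1.05 ± 0.14), Ms4a1 (0.97) and Cd74 (1.42), and Cd22 fell (10 and 1 adjusted over the list alone; adjusted p = 0.000113, and 0.0927 with an estimated correlation); among brighter genes the list was not called (adjusted p = 0.542, range 8.8e-05 to 0.542). Of 13 neutrophil markers 7 rose, with Ngp at 1.08, Mmp8 at 0.89 and Lcn2 at 0.54 (9 adjusted over the list alone; adjusted p = 2.9e-07, and 0.0927 with an estimated correlation). Jchain, a plasma cell gene, rose by 1.36. Most of these lay low, as with Cd79a at 28.2 in N1c and 58.6 in N1c_RBPJdel, and Mmp8 at 18.9 and 35.1. Myeloid markers (3 of 15 up; adjusted p = 0.0212, and 0.416 with an estimated correlation) and erythroid markers (3 of 9 up and 1, Tfrc, down; adjusted p = 0.0429, and 0.416 with an estimated correlation) were called higher, and both calls were lost with N1c_RBPJdel 2 alone (adjusted p = 0.370 and 0.0557, ranges 0.00427 to 0.899 and 0.0424 to 0.876). The dendritic cell (2 of 11 up), NK cell (2 of 11 up and 1 down) and platelet (0 of 8) lists were not called (adjusted p = 0.122, 0.957 and 0.622). In all, 1823 genes passed, 905 higher and 918 lower, 145 of them by at least 1 on the log2 scale, and the groups did not overlap for 16.4% of genes (5.71% by chance). The intensity range of the arrays differed as well: the interquartile range of log2 intensities was 2.58 and 2.56 on N1c_RBPJdel 1 and 3, 2.93 on N1c_RBPJdel 2 and 2.69 to 3.06 on the other 12 arrays. The count was 903 without N1c_RBPJdel 1, 3058 without N1c_RBPJdel 2, 964 without N1c 1 and 932 without N1c 2, 854 with N1c_RBPJdel 2 alone, 561 in the fit of the 2 groups alone, 3699 with the replicate block, 1187 among brighter genes and 2900 without control 5 and N1c 5. The balance depended on the setting: 531 were higher and 323 lower with N1c_RBPJdel 2 alone, 276 and 911 among brighter genes, and 47 and 98 for changes of at least 1.

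**Figure D3:**
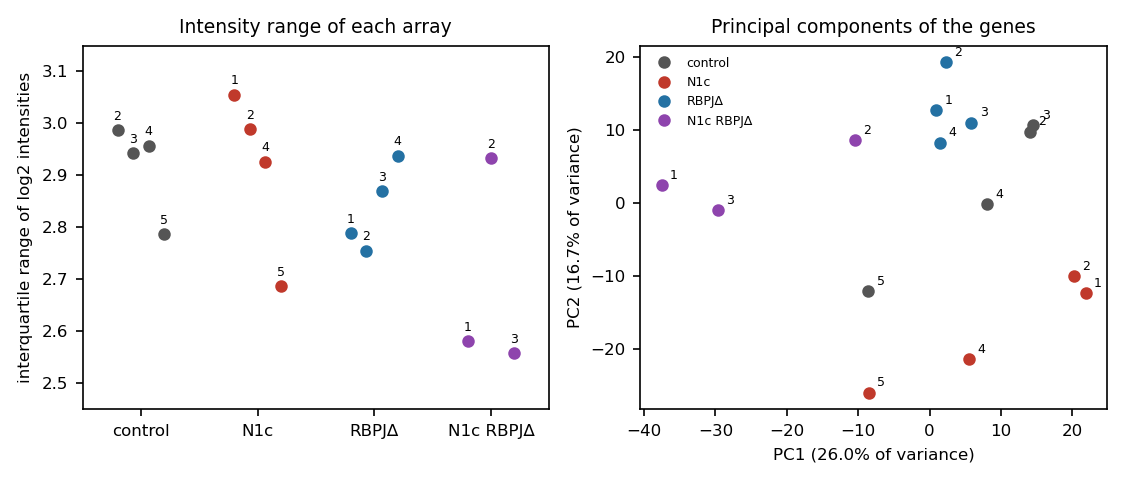
Left, interquartile range of log2 intensities (vertical axis) of each array by group, with replicate numbers; right, the arrays on the first and the second principal component of all genes (26.0% and 16.7% of the variance). N1c_RBPJdel 1 and 3 had the narrowest ranges, 2.58 and 2.56.

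Most genes of the N1c response were nearer to control in N1c_RBPJdel cells. Of the 326 genes called in N1c against control, 206 were called in the opposite direction in N1c_RBPJdel against N1c, 139 of the 185 that had risen and 67 of the 141 that had fallen, against 15.1 expected of independent lists. These comparisons share the N1c arrays; with the N1c arrays split into pairs a median of 112 genes (100 to 133) did so, against 3.58 expected. Mean intensity in N1c_RBPJdel was nearer to control than to N1c for 242 of the 326 (74.2%). The share of the N1c change left in N1c_RBPJdel had a median of 0.148 (SD 0.0288 over 3 arrays; quartiles -0.158 and 0.517), with 0.0511 for genes that had risen and 0.388 for genes that had fallen. Chosen and measured on separate arrays, the median share was 0.0483 (-0.0616 to 0.186 over 36 splits). It was 0.0731 for genes changed by at least 1 and 0.0985 without N1c 5.

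**Figure D4:**
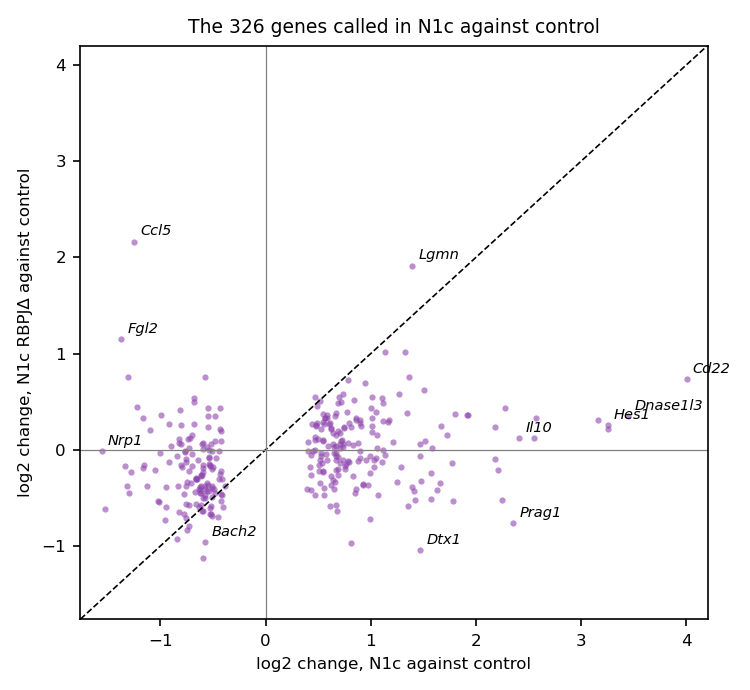
Log2 change in N1c_RBPJdel against control (vertical axis) over that in N1c against control (horizontal axis) for the 326 genes called in N1c against control; each point is a gene and the dashed line marks equal change. Cd22 lies at 4.00 and 0.73, Hes1 at 3.25 and 0.26, Nrp1 at -1.56 and -0.01, and Lgmn at 1.39 and 1.91.

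Comparing N1c_RBPJdel with control asked what remained or was added, but its changes include those of the deletion itself. Among the N1c genes, 55 were called in the same direction in both groups against control and 20 in the opposite direction; 14.2 in the same direction were expected of independent lists, and with the controls split into pairs there were 7 (3 to 13), against 1.76 expected. Of the 55, 14 had risen and 41 had fallen. Being called against control does not set them apart from the effect of the deletion. Of the 14, Cd22 and Scin also passed the test against RBPJdel and the others did not. Rnf157 changed by 0.63 here and by 0.53 in RBPJdel against control, and did not pass against RBPJdel (adjusted p = 0.680). Of the 41, some passed against RBPJdel, among them Bach2 (-0.74), and others, among them Cd55 (-0.08), did not. The 55 held Lgmn (1.91), which rose in RBPJdel too (1.49), and Cd22 (0.73). The call of Cd22 was lost without control 3 (adjusted p = 0.0595, range 0.00208 to 0.0635 over the alternatives). The repressor gene Bach2, which keeps T cells at rest, changed by -0.96 and Id2 by 0.73. Dtx1 changed by -1.04, a call lost without N1c_RBPJdel 1 (adjusted p = 0.0679) and with N1c_RBPJdel 2 alone (-0.36, adjusted p = 0.493; 0.00103 to 0.493 over the alternatives). Cd22, Bach2, Id2, Dtx1, Satb1, Ccr2, Rnf157, Scin and Cd55 were named here after their values were seen. Rnf157, Scin and Cd55 were not followed over the alternatives. Ccl5 rose by 2.16 ± 0.26, Car1 by 2.58 and Cxcr3 by 1.53, and Atp5md changed by -2.10, Foxn3 by -1.23 and Tbrg3 by -1.23. The resting T cell list had 7 of 14 members down, with Satb1 at -1.10 (1 and 8 adjusted over the list alone; adjusted p = 6.9e-07, and 0.0861 with an estimated correlation). The effector Treg list had 7 of 20 members up, with Ccr2 at 1.23 (10 and 0 adjusted over the list alone; adjusted p = 1.5e-05, and 0.191 with an estimated correlation), and the Th1 list 6 of 15 (7 and 0 adjusted over the list alone; adjusted p = 1.5e-05, and 0.0861 with an estimated correlation). B cell markers (7 of 15 up, 10 adjusted over the list alone; adjusted p = 3.7e-06, and 0.0841 with an estimated correlation) and neutrophil markers (6 of 13 up, 9 adjusted over the list alone; adjusted p = 1.0e-06, and 0.0861 with an estimated correlation) were higher in the same arrays. The test passed 1757 genes, 745 higher and 1012 lower, 47 of them by at least 1; the groups did not overlap for 18.7% of genes (5.71% by chance). The count was 1141 after quantile normalization, 1033 after cyclic loess, 839 with the array range as a covariate, 732 with N1c_RBPJdel 2 alone, 406 in the fit of the 2 groups alone, 3767 with the replicate block and 2785 without control 5 and N1c 5. It was 530 without N1c_RBPJdel 1, 3088 without N1c_RBPJdel 2, and 743, 675 and 850 without control 2, 3 and 4. More genes were higher than lower after cyclic loess (578 and 455), with N1c_RBPJdel 2 alone (445 and 287) and for changes of at least 1 (33 and 14), and 239 and 1141 were called among brighter genes.

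Comparing N1c_RBPJdel with RBPJdel asked what active Notch1 does where Rbpj is deleted. Hes1 (65.2 in RBPJdel and 78.3 in N1c_RBPJdel), Hey1 (92.8 and 129) and Heyl (a log2 difference of 0.14) did not pass the test, though Hey1 did so with the replicate block (adjusted p = 0.00973), after cyclic loess (0.0391), without N1c 5 (0.0494), without control 5 (0.0424) and without both (0.0312), with a range of 0.00973 to 0.150 over the alternatives. Of 15 Notch targets Dtx1 rose, by 1.08 ± 0.23 (n = 3 and 4), from 378 to 797 (2 up adjusted over the list alone; adjusted p = 0.527 for the list). The call of Dtx1 was lost without RBPJdel 1 (adjusted p = 0.0607) and without RBPJdel 3 (adjusted p = 0.0730; 0.00179 to 0.0730 over the alternatives). Cd22 rose by 1.12 ± 0.17, from 65.9 to 143; it, the Notch targets, Klrg1 and Ccr2 were named here after their values were seen. The chemokine gene Ccl3 rose by 1.21 and Car1 by 2.53, and Atp5md changed by -2.22, Kcnf1 by -1.25 and Cnpy2 by -1.04. The resting T cell list had 6 of 14 members down (8 adjusted over the list alone; adjusted p = 5.4e-07, and 0.0868 with an estimated correlation), and the effector Treg list 2 of 20 up (4 adjusted over the list alone), with adjusted p = 4.7e-05, and 0.203 with an estimated correlation. These were Klrg1 (1.06) and Ccr2 (0.93), and the call of Ccr2 was lost without N1c_RBPJdel 1 (adjusted p = 0.0884) and with N1c_RBPJdel 2 alone (adjusted p = 0.157; 0.0123 to 0.157 over the alternatives). The cell cycle list was called lower (0 of 35 past the test, 6 adjusted over the list alone; adjusted p = 1.5e-08, and 0.257 with an estimated correlation). B cell markers (4 of 15 up, 7 adjusted over the list alone; adjusted p = 6.1e-06, and 0.0868 with an estimated correlation) and neutrophil markers (5 of 13 up, 7 adjusted over the list alone; adjusted p = 2.0e-07, and 0.0868 with an estimated correlation) were again higher. The test passed 452 genes, 261 higher and 191 lower, and the groups did not overlap for 15.8% of genes (5.71% by chance). The count was 76 without N1c_RBPJdel 1, 1890 without N1c_RBPJdel 2, 121, 112 and 79 without RBPJdel 1, 2 and 3, and 300.0 without control 3. It was 226 with N1c_RBPJdel 2 alone, 192 among brighter genes, 98 in the fit of the 2 groups alone, 2107 with the replicate block and 1049 without control 5 and N1c 5. More genes were lower than higher among brighter genes (148 and 44), with the replicate block (1189 and 918), without N1c_RBPJdel 2 (985 and 905) and without control 5 and N1c 5 (538 and 511).

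The interaction asked whether the effect of N1c differed between cells with and without the deletion of Rbpj. The effect was smaller with the deletion for Dnase1l3 (a difference of -3.11 ± 0.27), Atp8a2 (-3.07), Hes1 (-2.99 ± 0.36), Cd22 (-2.88), Heyl (-2.43) and Hey1 (-1.80), and for Nrp1 the difference was 1.37. Of 15 Notch targets 4 had a lower effect (4 adjusted over the list alone; adjusted p = 3.5e-06, and 0.0435 with an estimated correlation), and the cell cycle list was called lower (2 of 35 members past the test, 27 adjusted over the list alone; adjusted p = 2.6e-24, and 0.149 with an estimated correlation). Of the 326 N1c genes 101 passed this test in the opposite direction. In all, 166 genes passed, 63 with a positive and 103 with a negative difference. The count was 478 without N1c_RBPJdel 2 and 101, 102 and 101 without RBPJdel 1, 2 and 3, array weights gave 257 and the replicate block gave 632. Positive differences were the more frequent with N1c_RBPJdel 2 alone (71 against 45) and without N1c_RBPJdel 3 (88 against 80).

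**Figure D5:**
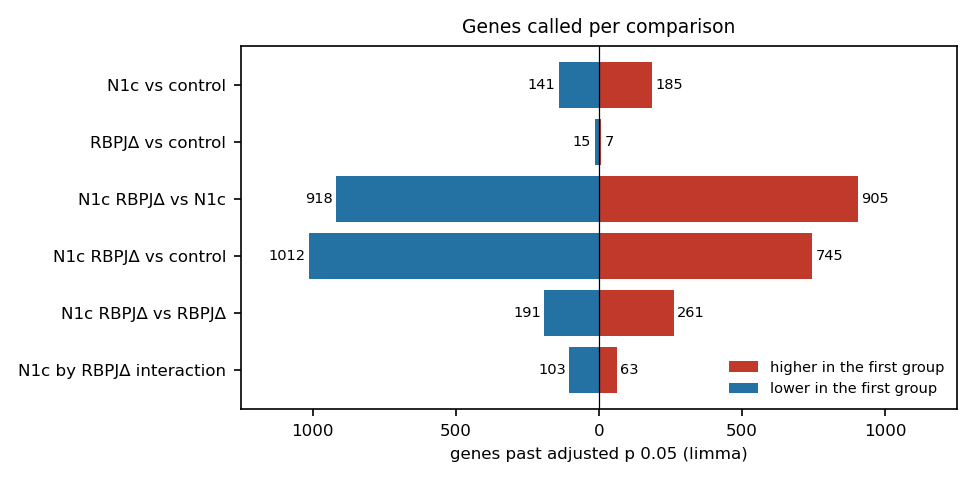
Genes past adjusted p 0.05 in limma (horizontal axis, number of genes) in each of the 6 comparisons (vertical axis), higher in the first group to the right and lower to the left. N1c against control had 185 and 141, and RBPJdel against control 7 and 15.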

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

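The tests of genes called before and after quantile normalization, of RNA from other cells and of the array quality of N1c_RBPJdel 1 and 3 were chosen after the results they measure were seen, as were the markers given with intensities. The rule for the direction of the called genes was changed after its values were seen.

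The effect of N1c differed between cells with and without the deletion of Rbpj by the interaction test for 166 genes. The difference was -3.11 for Dnase1l3, -3.07 for Atp8a2, -2.99 for Hes1, -2.88 for Cd22 and -2.64 for Atp5md on the log2 scale. It was 2.55 for Car1, 2.02 for Rln3, 1.83 for Penk, 1.78 for Ccl5 and 1.68 for Fgl2. Car1 and Atp5md were not called in N1c against control, so that their differences rest mainly on the N1c_RBPJdel arrays. The sorter cannot be told apart from the genotype in those arrays. The calls of Car1 and Ccl5 were lost without RBPJdel 2 (adjusted p = 0.0556 and 0.0581, ranges 3.7e-05 to 0.0556 and 0.00292 to 0.0679 over the alternatives). That of Fgl2 was lost with N1c_RBPJdel 2 alone (adjusted p = 0.0540, range 0.00237 to 0.0540).

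In each comparison, 1 split of the arrays gave as many genes as the real groups, the real one itself. This argues against chance for RBPJdel against control and for the 3 comparisons of N1c_RBPJdel with another group, over these splits. The share, 2.86%, is the smallest that 35 splits can give, and it was not adjusted over the comparisons. For N1c_RBPJdel it does not tell the genotype from the sorter. RBPJdel 4 and control 4 also went together (r = 0.417), although the rule did not pair their groups. The rank of the real split cannot exclude chance for N1c against control, whose arrays were paired. Nor can it for the interaction, where the drawn splits mixed all 4 groups and so put group effects into the spread. There were 35 splits for each pair of groups and 100 for the interaction, the real one included and the others drawn. The real count and the highest of the other splits were 326 and 139 for N1c against control and 22 and 2 for RBPJdel against control. They were 1823 and 1294 for N1c_RBPJdel against N1c, 1757 and 1531 against control and 452 and 43 against RBPJdel, and 166 and 6 for the interaction. The high counts of other splits against N1c and control point to a structure of the samples: the highest set N1c_RBPJdel 1 and 3, of narrow intensity range, with N1c 5 or with control 5, the narrowest of their groups, apart from the rest. The next, with 1245 and 944 genes, moved N1c 5 or control 5 to the side of all 3 N1c_RBPJdel arrays, N1c_RBPJdel 2 with its range of 2.93 included. For N1c and control, whose numbers pair the arrays, 8 splits part all 3 pairs, too few for a share under 0.05. Among these the real count was 326 and the highest other 0, and the split with 139 genes parted none of the pairs.

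Many genes differed between N1c_RBPJdel and control, 1757 in all, and the narrow intensity range of N1c_RBPJdel 1 and 3 is a candidate explanation. Of these genes 841 were called in the same direction after every array was given 1 distribution, with a median size of change of 0.59 before and 0.55 after, so the range is not the whole cause for them. A narrower range moves genes toward the median gene, as did 86.4% of the 1757, 73.2% of the 841 and 69.1% of all genes, which leaves it open for the 916 called on the deposited values alone. With the range as a covariate 839 genes were called, and 732 with N1c_RBPJdel 2 alone, both between the bounds set in advance for the count as a whole. The sorter cannot be told apart from the genotype, since 0 N1c_RBPJdel arrays came from the MoFlo, and RBPJ-independent action of Notch1 stays open, untested.

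RNA of other cells is a further candidate explanation for marker genes that rose in the same comparison. The median changes of the B cell, myeloid, neutrophil and erythroid lists lay at percentiles 100, 99.87, 99.98 and 99.9 of 10000 random lists of like size and intensity. Those of the dendritic cell, NK cell and platelet lists, however, lay at 58.2, 57.0 and 68.6. Those of the CD8 and the conventional CD4 T cell markers lay at 99.72 and 94.22. These T cell lists share 7 of 9 and 3 of 8 members with other lists. The gate on B220, CD11b, CD11c and Gr1 would remove most B cells, myeloid cells and neutrophils, but it holds no marker of erythroid cells. The cells were also selected for CD3, TCR beta, CD4 and the green fluorescent protein, which would leave out most other cells, erythroid ones too. Of the B cell, myeloid, neutrophil and erythroid markers 3 of 15, 3 of 15, 1 of 13 and 2 of 9 lay above the median gene in control Treg, and 0 belonged to another list. Of the 3 brightest markers of each list, Cd74 (315 to 635), Cd22 (86.1 to 143), Mmp9 (149 to 241) and Slc4a1 (106 to 169) rose and Tfrc (277 to 167) fell, while Cd79b (376 to 432), Ctss (1066 to 1011), Cd68 (160 to 121), Cebpb (112 to 108), Mpo (75.9 to 94.5), Camp (79.2 to 95.6) and Gata1 (312 to 252) were not called. The calls of Cd74, Cd22 and Mmp9 were lost without control 3 (adjusted p = 0.0556, 0.0595 and 0.0767, ranges 0.00263 to 0.0959, 0.00208 to 0.0635 and 0.00341 to 0.0919 over the alternatives), those of Cd74 and Mmp9 also without N1c_RBPJdel 1 or control 2, that of Cd74 without control 4 and that of Mmp9 without N1c_RBPJdel 2. That of Slc4a1 was lost with N1c_RBPJdel 2 alone (adjusted p = 0.10, range 0.00650 to 0.10), with which Cd79b was called (adjusted p = 0.0147, range 0.0147 to 0.933). Camp was called without control 5 and N1c 5 (adjusted p = 0.0410, range 0.0410 to 0.898) and Gata1 with the replicate block (adjusted p = 0.0165, range 0.0165 to 0.956). Brightness was the mean over all arrays, among them the N1c arrays, on which Cd22 lay at 1379.7. As Cd22 rose with N1c itself, its rise here is no separate sign of B cells. Cd74 lay at 500.3 in RBPJdel arrays too. The globin genes were not measured. The Treg signature list had a median of -0.0327 and a lower quartile of -0.15, against a median of -0.50 for the genes that fell. These values argue against dilution of Treg RNA as the only cause of those falls. A weaker dilution is not excluded, since those genes were chosen for their fall and Fgl2 of the list changed by 1.15.

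Atp5md and H2-Ea differed in N1c_RBPJdel from the 3 other groups, and a linked stretch of another strain's chromosome was set against array quality, where H2-Ea was chosen after its values were seen. Atp5md fell alike on its 3 probe sets (-2.40, -2.47 and -2.52 against N1c), and H2-Ea rose from 38.5 in control to 91.0 (1.24, adjusted p = 5.4e-05). Of 40 measured neighbours of each gene, 1 was called around Atp5md in N1c_RBPJdel against RBPJdel (Sfxn2, percentile 42.1 of all such windows). None was called around H2-Ea. The percentile counts windows with a smaller share called, so H2-Ea has percentile 0, as any window without a call does. The median window had 2.5% called. These values argue against a stretch with many genes called in this comparison, but a stretch with few is not excluded. N1c_RBPJdel 2 also lay outside the other 12 arrays, at 708 for Atp5md (2292 to 4239) and 91.3 for H2-Ea (33.7 to 46.3). Atp5md was named among genes whose arrays do not overlap and H2-Ea after its values were seen, so the choice fixed this outcome. It therefore cannot exclude the quality of replicates 1 and 3. A variant of the single gene, the sorter and the genotype stay open, untested. So does RNA of other cells for H2-Ea, a gene of antigen-presenting cells. Of the same cells, Cd74 did not stand apart alike (500.3 in RBPJdel and 635 in N1c_RBPJdel). H2-Ab1, of the dendritic cell list, was however called higher in N1c_RBPJdel than in N1c. Its change there was 0.67 to 0.93 over the alternatives, 4 of which ended the call.

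Values of 1 array far from the other 3 of its group were found in 32 of 366 groups of values, those of the 121 named genes and of the interquartile range of the arrays in the 3 groups of 4. Chance flags about 1 in 20 groups, or 18.3 here. On control 5 these were Cd74 (384), Clec9a (34.3), Ifih1 (549.7), Notch1 (836), Slamf6 (2859) and Spen (566). On the other control arrays they were Il4 (51.8), Naip6 (269) and Rbpj (571) on control 2, Rab6b (473) on control 3 and Tigit (1024) on control 4. On N1c 1 they were Ms4a1 (31.4), Spi1 (47.2) and Themis (1093), on N1c 2 Gzma (33.3), Rab6b (341) and Zfp979 (10.7), on N1c 4 Kif11 (139.9) and on N1c 5 Fcer1g (72.8) and Il4ra (767). On RBPJdel 1 they were Maf (650.2) and Rab6b (271), on RBPJdel 2 Ngp (24.9) and Slc4a1 (144), on RBPJdel 3 Klrd1 (21.1), Pde3b (47.5) and Tigit (2099), and on RBPJdel 4 Foxn3 (856), Lgmn (754), Rrm2 (119), Tbrg3 (342) and Ube2c (98.4).

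Among 3497 features that name several genes or none, which no comparison used, some passed the same test. There were 37 in N1c against control, 1 in RBPJdel against control, 337, 303 and 96 in N1c_RBPJdel against N1c, control and RBPJdel, and 47 in the interaction.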

How the results depend on the processing

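The array range covariate, N1c_RBPJdel 2 alone, the joint removal of control 5 and N1c 5 and 4 settings of the list tests were chosen after the data were seen. Over named genes and lists, 7820 values of 393 results were recomputed: 7048 kept direction and side of the threshold, 688 lost the call, 77 gained it and 7 reversed. The sorter could not be separated from the genotype and was not run, and the neutrophil list had too few members among brighter genes. Array signal near background limits what can be said of dim genes. Except where fewer genes, arrays or a stricter or looser threshold make the difference by construction, the cause was not tested.

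Counts of genes moved by over 1.5 times as follows. Array weights gave 733 in N1c against control (326 reported), 189 in RBPJdel against control (22) and 257 in the interaction (166). The replicate block was fitted to all groups, though the rule paired N1c and control alone. It gave 494 in N1c against control and 632 in the interaction. In N1c_RBPJdel against N1c, control and RBPJdel it gave 3699, 3767 and 2107 (1823, 1757 and 452). The fit of the 2 groups alone gave 561, 406 and 98 in these 3. A log2 change of at least 1 left 84, 12, 145, 47, 23 and 90 in the 6 comparisons, and an adjusted p of 0.1 gave 3125, 3128, 1360 and 325 in the last 4. Brighter genes gave 1187 against N1c and 192 against RBPJdel. Against control, quantile normalization gave 1141 (841 shared in direction), cyclic loess 1033 and the range covariate 839. N1c_RBPJdel 2 alone gave 854, 732 and 226, and the removal of control 5 and N1c 5 gave 2900, 2785 and 1049. With each array left out in turn the counts ran from 217 to 383 in N1c against control, 17 to 26 in RBPJdel against control, 903 to 3058, 530 to 3088 and 76 to 1890 in N1c_RBPJdel against N1c, control and RBPJdel, and 101 to 478 in the interaction. In the 3 comparisons of N1c_RBPJdel with another group the lowest count was without N1c_RBPJdel 1 and the highest without N1c_RBPJdel 2.

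The median share of the N1c change left, 0.148, was 0.0483 with genes chosen and measured on separate arrays, 0.182 after cyclic loess, 0.0731 at a log2 change of at least 1, 0.180 with the block, 0.197 with N1c_RBPJdel 2 alone, and 0.0985 to 0.197 with each array left out. The correlation of the N1c and RBPJdel changes, 0.184, was -0.0616 with the controls split and 0.145 to 0.287 with each array left out. Lists that reversed were not called then (adjusted p): among brighter genes the myeloid markers against N1c (0.899) and control (0.969) and the B cell markers in the interaction (0.810), after quantile normalization the ribosomal proteins in the interaction (0.991), and with N1c_RBPJdel 2 alone glycolysis against RBPJdel (0.468) and in the interaction (0.472). The immediate early list against RBPJdel reversed and was called with the block (0.0381).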

Other observations

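The test of a share of cells that kept RBPJ was chosen after the result was seen, and its rule was changed again after that. The rule for the narrow range and the share left was also changed after its value was seen.

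Genes of mTOR and PI3K-Akt signalling were lower in N1c_RBPJdel than in control, 5 of 23 members (6 adjusted over the list alone; adjusted p = 2.9e-05, camera, and 0.0996 with an estimated correlation). Foxo1, a transcription factor restrained by Akt, changed by -0.61, a call lost with N1c_RBPJdel 2 alone (-0.42, adjusted p = 0.125, range 0.00243 to 0.125 over the alternatives). Rictor, a part of an mTOR complex, changed by -0.43, a call lost without N1c_RBPJdel 1 (adjusted p = 0.0507) and after quantile normalization (adjusted p = 0.0758, range 0.00648 to 0.119). Both were chosen after their values were seen. With N1c_RBPJdel 2 alone the list was not called (adjusted p = 0.0712, range 4.1e-05 to 0.0996). CD8 T cell markers were higher, 4 of 9 members (4 adjusted over the list alone; adjusted p = 0.00475, and 0.108 with an estimated correlation), of which Ccl5 changed by 2.16. Cd8a itself had a difference of -0.13 (adjusted p = 0.686) and Cd8b1 of 0.11 (adjusted p = 0.644), both seen before they were chosen. Of these 9 markers 7 are in another list too.

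Against RBPJdel, the interferon response list was called lower in N1c_RBPJdel, with 1 of 26 members past the test (7 adjusted over the list alone; adjusted p = 0.00187, and 0.257 with an estimated correlation). So were glycolysis genes (0 of 18; adjusted p = 0.00217, and 0.275 with an estimated correlation) and ribosomal proteins (0 of 21, 3 adjusted over the list alone; adjusted p = 0.00171, and 0.325 with an estimated correlation). After quantile normalization none of these 3 lists was called (adjusted p = 0.0746, 0.0605 and 0.425, ranges 0.00083 to 0.257, 0.00614 to 0.468 and 0.00270 to 0.425).

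Part of the N1c effect was left in N1c_RBPJdel, a median share of 0.148, and a share of cells that kept RBPJ is a candidate explanation. On the linear scale such cells would leave the same share of rises and falls. On N1c_RBPJdel 1, 2 and 3 the median share of the rise was 0.00471, 0.128 and -0.0148 and that of the fall 0.496, 0.225 and 0.479 from control, and 0.0368, 0.157 and 0.0330 against 0.474, 0.194 and 0.507 from RBPJdel. The fall kept the larger share on each array, which argues against such cells as the only cause, but the gap was wide on the 2 arrays of narrow range alone, and neither these cells nor RBPJ-independent action of Notch1, untested, is excluded. The narrow range of these arrays is not excluded either: the share was 0.197 with N1c_RBPJdel 2 alone, at least as large as with all 3, but this is 1 array and genes chosen on the N1c arrays that set the share, and genes chosen and measured on separate arrays left 0.0483 (-0.0616 to 0.186).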
